A study of Mus musculus with 12 samples.

How the data were processed

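Heart RNA of C57BL/6J mice was sequenced in 12 libraries, 3 in each of 4 groups: control, PLX3397, sorafenib, and sorafenib with PLX3397. Per the labels, the hearts were taken after 28 days of sorafenib in the presence or absence of a macrophage clearance agent. Per the labels' protocols, total RNA was extracted with Trizol, poly(A) RNA was selected on oligo(dT) beads, and a second strand labelled with dUTP was made. The labels give no dose, route, sex, age, time of day of sampling or sequencing date, and do not say whether each library is a separate animal.

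The deposited table held 1 row per gene for 30199 genes, with an estimated count column and an FPKM column for each library. Per the submitters' processing notes, DESeq2 and edgeR were used on the mm10 build; their versions, the aligner and the program that counted reads are not given in the sources used here. The deposited estimated counts were whole numbers, with 12143 values equal to 4 against 5303 equal to 3 and 3364 equal to 5, so low values piled up at multiples of 4. Whether they count single fragments is not known. The deposited FPKM values were scaled for gene length and library size by the authors, per the file headers, and were used here for 1 alternative and for the minimum level of named genes. Of the gene identifiers, 30109 (99.7%) were in GENCODE vM21, and 90.4% of the genes had the same start and end there. Symbols, identifiers and coordinates were used as deposited. Because the counting program and its use of strand are unknown, values of overlapping, antisense and near-identical genes are uncertain.

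Total estimated counts per library ranged from 61626404 to 64537365. Mitochondrial genes took 29.3% to 33.7% of them. The tests use the spread between libraries and thus cover counting error and variation between samples together. They measure only the spread between these samples.

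Groups were taken from the sample titles. Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes with low counts were removed with filterByExpr (minimum count 10, minimum total 15), which left 18897 genes, libraries were scaled by TMM, and a robust quasi-likelihood model with 1 mean per group was fitted to all 12 libraries. All groups then shared 1 estimate of the spread. The contrasts were sorafenib versus control, PLX3397 versus control, sorafenib with PLX3397 versus sorafenib, sorafenib with PLX3397 versus PLX3397, and their interaction, the difference between the sorafenib effect with and without PLX3397. The p-values were two-sided and were adjusted by the Benjamini-Hochberg method over all genes of a contrast, and genes with an adjusted p under 0.05 were called. Standard errors (SE) of log2 fold changes were derived from the quasi-likelihood F statistic. The contrasts, the test, the gene lists and the rule for named genes were fixed before the data were examined. Sorafenib with PLX3397 versus control was added after results had been seen and appears only among the other observations.

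The named genes were Pde2a, Csf1r, Adgre1, Cd68, C1qa, Nppa, Nppb, Myh7, Col1a1 and Postn whatever their result. Further named genes were the 8 largest rises and the 8 largest falls among called genes with a mean of at least 1 FPKM, a symbol that is not a predicted or clone name, and no overlap between the libraries of both groups. From each gene list that passed its test, up to 4 called members with the smallest p were added. Any other gene is named as chosen after its values were seen.

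35 gene lists for cell types and processes were tested in the 5 planned contrasts, 175 tests, with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over all 175 tests. The same tests were made with an estimated correlation and with fry. Of the 175 tests, 69 passed with the preset correlation, 0 with the estimated correlation and 9 with fry. Called members are counted over all genes tested and, separately, adjusted over the list alone. KEGG and Gene Ontology terms were tested with Fisher's exact test against the tested genes that carry an annotation, as an exploration. List scores per library are the mean over genes of log2 CPM minus the mean of the controls.

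The alternatives were no filter and a stricter filter on low counts (1 CPM in 3 libraries), the size factors and the Wald test of DESeq2 1.42.0, limma on log2 of the deposited FPKM plus 0.5, the replicate number as a block, only the groups compared, an added limit of a 2-fold change, and leaving out each library in turn. Each fit without a library ran the filter on low counts again on the remaining libraries, so its set of genes changed too. After the data were examined, counts divided by 4 and the removal of mitochondrial genes were added. Alternatives planned for FPKM as the main unit were not run because counts were available. The model was tested on simulated counts with known changes at 1.5, 2 and 4-fold. The changed genes were drawn from those with a mean of at least 1 FPKM, and the macrophage markers were set 2-fold lower as well. Counts were drawn independently for each gene, without correlation between genes or the pile-up at multiples of 4. The rates therefore do not carry over to genes of lower level or to correlated data. In the simulated sorafenib versus control contrast it recovered 44.8%, 86.6% and 97.0% of the changed genes at these sizes with 8 false calls among 18426 genes. In the simulated PLX3397 versus control contrast it recovered 52.2%, 85.1% and 93.9%, with 5 false calls among 18411 genes.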

Results

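Gene expression was measured by poly(A) RNA sequencing in 12 mouse heart samples, 3 per group: controls, hearts labelled with the macrophage clearance agent PLX3397, with sorafenib, or with both. Sorafenib was given for 28 days, per the labels. PLX3397 inhibits the receptor CSF1R, on which tissue macrophages depend, and sorafenib is a kinase inhibitor used against cancer that can harm the heart. The study's title concerns the phosphodiesterase PDE2A of macrophages. Heart RNA gives Pde2a over all cell types together and does not show its level in macrophages. Total estimated counts ranged from 61626404 in PLX3397 replicate 2 to 64537365 in control replicate 3, and 21862 to 22554 genes per library had a count above 0. Correlations of log2 CPM between libraries of the same group were 0.972 to 0.981. The first principal component held 25.3% of the variance. On it the controls lay at -41.8, -41.0 and -55.7, PLX3397 replicate 1 at -41.8, and PLX3397 replicates 2 and 3 at 6.66 and 6.07. Sorafenib libraries lay at 12.5 to 23.7 and those with both agents at 32.3 to 47.5. The values that follow are log2 fold changes ± SE with n = 3 libraries per group, and adjusted p-values are from the quasi-likelihood test of edgeR.

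Resident macrophage markers give a check of the labels, because the agent labelled PLX3397 is meant to remove these cells. Relative to the controls, the mean log2 CPM of 30 such markers was -0.05, -0.16 and -0.18 in the libraries labelled PLX3397. It was -1.30, -1.31 and -0.59 in those labelled sorafenib and -1.88, -1.48 and -1.49 in those labelled with both. The marker level was thus lowest with both agents and lower with sorafenib than with PLX3397. Csf1r itself had 53.7 ± 5.38 CPM (SD, n = 3) in controls, 44.2 ± 7.30 with PLX3397, 23.9 ± 5.77 with sorafenib and 14.4 ± 2.10 with both. The labels are therefore written as given, as the library's label, and each direction below depends on them.

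**Figure D1:**
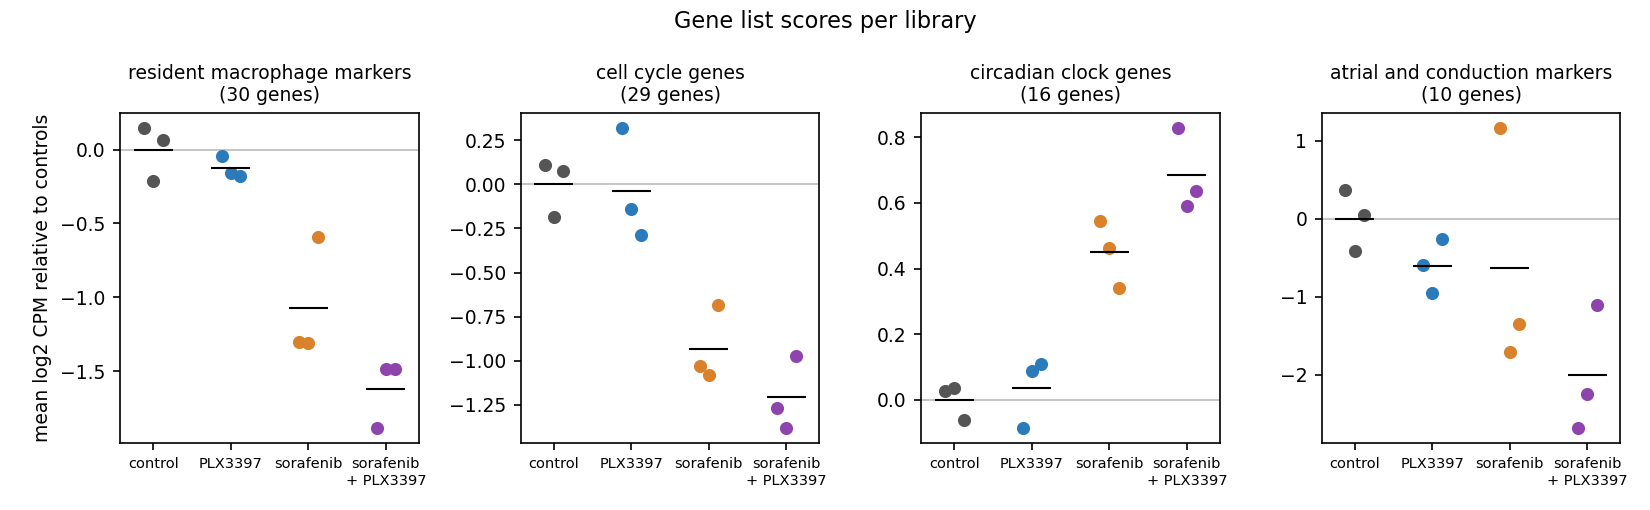
Mean log2 CPM of the genes of 4 lists, relative to the control mean, per library (points) and group (line: mean of 3). Macrophage markers lay at -0.05 to -0.18 in the PLX3397 libraries and at -0.59 to -1.31 in the sorafenib libraries.

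The comparison of sorafenib with control asks what the drug changed in the heart. Expression of resident macrophage, antigen-presentation and cell cycle genes was lower in the hearts labelled sorafenib. Genes of the circadian clock changed in both directions, and several contractile and calcium-handling genes of cardiomyocytes rose. The xenobiotic-response gene Cyp1a1 rose by more than any other named gene. Pde2a and the natriuretic peptide genes did not pass the test, and no gene list passed with an estimated correlation. The lists that passed with fry were clock genes (adjusted p = 0.0115), cytokine and chemokine genes (adjusted p = 0.0115), resident macrophage markers (adjusted p = 0.0164) and cell cycle genes (adjusted p = 0.0283). Of 18897 genes, 500 were called, 284 higher and 216 lower. At least 2-fold changes were seen in 136 of them, 30 higher and 106 lower. In a fit of only the 2 groups compared, 182 were higher and 278 lower of 460 called. With limma on the deposited FPKM, which moved the median of all genes by -0.11, the split was 115 higher and 856 lower of 971 called.

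Among macrophage genes, Csf1r fell (-1.17 ± 0.17, adjusted p = 0.00733) and C1qa fell (-1.27 ± 0.22, adjusted p = 0.0181). Adgre1, the gene of the macrophage antigen F4/80, had a value of -0.98 ± 0.27 (adjusted p = 0.0700), and Cd68 one of -0.57 ± 0.22 (adjusted p = 0.165). Without sorafenib replicate 3 both passed, with Adgre1 at -1.41 and Cd68 at -0.85. The phosphatidylserine receptor gene Timd4 (-2.54), the folate receptor gene Folr2 (-2.17), the Fc receptor-like gene Fcrls (-1.79) and the endotoxin co-receptor gene Cd14 (-1.45) fell. So did Cybb (-1.65), which encodes a subunit of the phagocyte oxidase, Wfdc17 (-1.64), Ptpn6 (-1.56) and the activation marker Cd83 (-1.90). Of 30 resident macrophage markers, 14 fell and 0 rose over all genes, and 22 fell when adjusted over the list alone. The median was -1.01 (adjusted p = 6.69e-27; adjusted p = 0.208 with an estimated correlation). The MHC class II genes H2-Ab1 (-1.48), H2-Eb1 (-1.29) and Cd74 (-1.32) fell. They were 3 of the 16 dendritic cell and MHC class II genes, of which 7 fell when adjusted over the list alone (median -1.08, adjusted p = 5.37e-07; adjusted p = 0.374 with an estimated correlation). Among 28 cytokine and chemokine genes, Il1b (-2.13) and Ccl9 (-0.81) fell, over all genes and adjusted over the list alone (median -0.52, adjusted p = 0.00152; adjusted p = 0.173 with an estimated correlation). KEGG's phagosome term held 14 of its 141 tested genes among those that fell, against 2.67 by chance (adjusted p = 7.57e-05, Fisher's exact test).

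Genes of dividing cells were lower as well. Tpx2 (-1.59), Top2a (-1.34), Ccna2 (-1.13) and Bub1 (-1.70) fell, with mean levels under 1 FPKM. Of 29 cell cycle genes, 7 fell over all genes, and 24 fell and 1 rose when adjusted over the list alone (median -0.96, adjusted p = 5.64e-15; adjusted p = 0.268 with an estimated correlation). Phgdh, of serine synthesis, had the largest fall among the genes chosen by size (-2.36 ± 0.36, adjusted p = 0.00913). Psat1 (-0.88), of the same pathway, and the amino acid transporter gene Slc7a5 (-0.91) fell too. These 3 were the called members of 21 integrated stress response genes, of which 7 fell and 1 rose when adjusted over the list alone (median -0.33, adjusted p = 0.00498; adjusted p = 0.376 with an estimated correlation), with a median of -0.18 without sorafenib replicate 2. Of 19 unfolded protein response genes, 0 were called by edgeR over all genes, and 13 fell and 1 rose when adjusted over the list alone (median -0.37, adjusted p = 9.00e-05; adjusted p = 0.488 with an estimated correlation). Control replicate 3 stood apart in that list, with a score of 0.31 against -0.17 and -0.14 in the other controls, and the median was -0.21 without it.

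Clock genes rose in the hearts labelled sorafenib: Dbp by 1.74 ± 0.22 (adjusted p = 0.00733), Ciart by 1.46, Per2 by 1.40, Per3 by 1.29, Nr1d2 by 0.89 and Tef by 0.79. Arntl, which encodes the core clock factor BMAL1 and was chosen after its values were seen, fell (-1.31, adjusted p = 0.0301). Of 16 clock genes, 10 rose and 2 fell over all genes, and 10 rose and 4 fell when adjusted over the list alone (median 0.76, adjusted p = 1.77e-08; adjusted p = 0.173 with an estimated correlation). Cyp1a1 rose by 3.81 ± 0.33 (adjusted p = 0.00188), from 4.0 ± 1.40 CPM (SD, n = 3) to 56.0 ± 9.69 CPM. Other rises were those of Bmp4 (1.20), Tmem252 (1.17) and Mir208b (1.48), a microRNA gene within Myh7 whose reads cannot be told apart from those of its host.

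Among cardiomyocyte genes, the ryanodine receptor gene Ryr2 (0.70), the calcium channel gene Cacna1c (0.55), the myosin gene Myh6 (0.56) and the Z-disc gene Tcap (0.59) rose. They were 4 of 18 cardiomyocyte markers, of which 7 rose when adjusted over the list alone (median 0.19, adjusted p = 0.00282; adjusted p = 0.376 with an estimated correlation), and the list did not pass without control replicate 1, at a median of 0.16. Ppargc1a (0.75), a regulator of mitochondrial metabolism, and Acot2 (0.60) rose, 2 of 27 fatty acid genes (5 adjusted over the list alone). The median of that list was 0.07 (adjusted p = 0.00762; adjusted p = 0.608 with an estimated correlation) and -0.05 with limma on FPKM. It did not pass without control replicate 1, at 0.08, or without sorafenib replicate 3, at 0.03, and was 0.12 without sorafenib replicate 1 or 2. The 13 mRNAs of the mitochondrial genome had a median of 0.25, with 0 called by edgeR over all genes and 9 risen when adjusted over the list alone (adjusted p = 1.83e-05; adjusted p = 0.459 with an estimated correlation). The 54 nuclear genes of oxidative phosphorylation had a median of -0.12 with 0 called by edgeR over all genes or adjusted over the list alone (adjusted p = 0.00539; adjusted p = 0.765 with an estimated correlation). That list did not pass without control replicate 2 (-0.08), control replicate 3 (-0.05) or sorafenib replicate 1 (-0.08), and had a median of -0.21 without control replicate 1. Adcy6, an adenylate cyclase gene, rose (0.65).

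Pde2a (chromosome 7, 101421691 to 101512827, mm10) had 56.7 ± 6.73 CPM (SD, n = 3) in controls and 73.2 ± 5.43 CPM with sorafenib, a value of 0.37 ± 0.13 (adjusted p = 0.134). Nppa had a value of 0.08 ± 0.74 with 576 ± 650 CPM (SD, n = 3) in the sorafenib libraries, and Nppb one of -0.88 ± 0.46 (adjusted p = 0.319). The Nppa value rested on sorafenib replicate 1, with 1324 CPM against 251 and 152 in replicates 2 and 3. The atrial and conduction markers stood apart in the same library, with a score of 1.17 against -1.71 and -1.36 in replicates 2 and 3. The Nppa value thus cannot be read as a stress response alone. Nppa was at -1.43 without that library (adjusted p = 0.164), and at -0.17 to 0.55 when any other control or sorafenib library was left out. Myh7 (0.24), Col1a1 (-0.07) and Postn (-0.14) did not pass either. Fibroblast markers had a median of -0.05 and endothelial markers one of -0.04. The count of 500 changed when single libraries were left out, which also made a group smaller and reran the filter on low counts. It was 1422, 101 and 45 without control replicates 1, 2 and 3. It was 27, 183 and 474 without sorafenib replicates 1, 2 and 3. Of 39 called genes named here by rule, Cyp1a1, Nr1d2, Tef, Ppargc1a, Fcrls, Timd4, Cybb, Cd83 and Phgdh were called in every alternative other than the limit of a 2-fold change, which was applied only to counts.

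**Figure D2:**
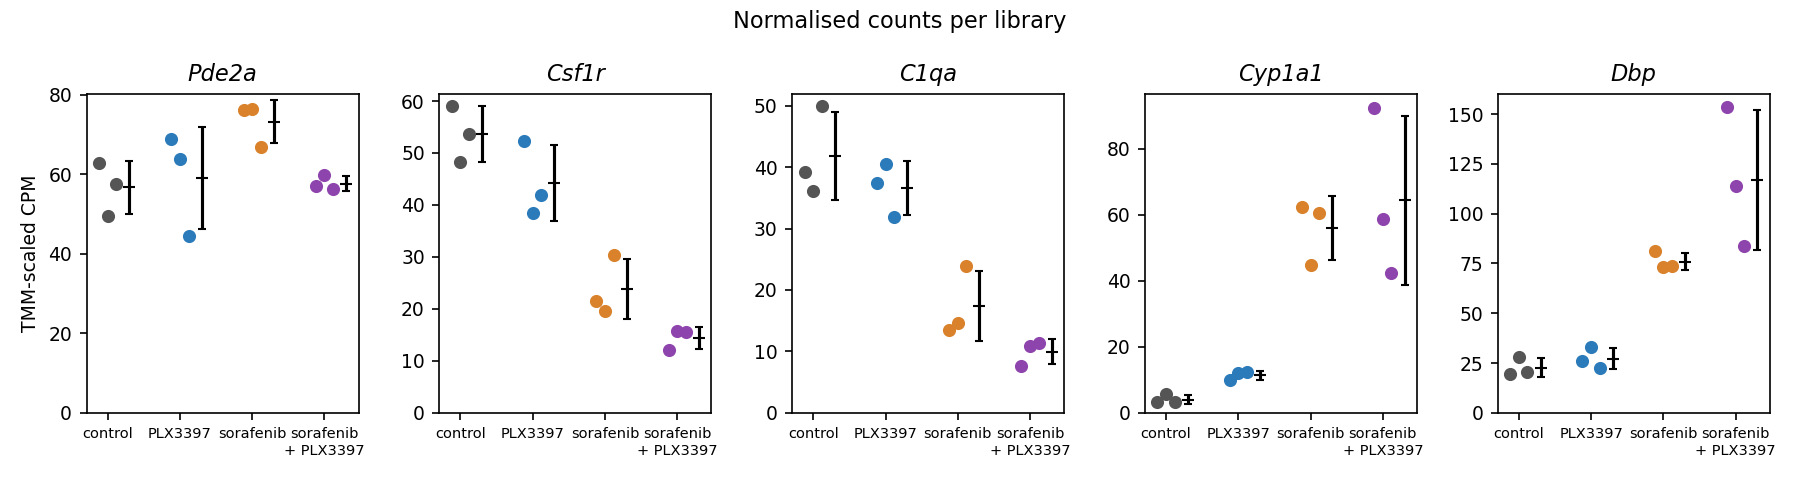
Normalised counts (TMM-scaled CPM) of 5 genes per library (points), with the group mean and SD (bars, n = 3). Csf1r averaged 53.7 CPM in controls and 14.4 CPM with both agents, while Pde2a averaged 56.7 and 57.6 CPM.

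The comparison of PLX3397 with control concerns the agent meant to clear macrophages, given alone per the labels. No gene was called in the hearts labelled PLX3397, and the macrophage markers did not pass as a list. edgeR called 0 genes with 2325 at an unadjusted p under 0.05 and a smallest adjusted p of 0.361. DESeq2's Wald test called 100, 83 higher and 17 lower, and limma on FPKM called 0. Without PLX3397 replicate 1 the count was 578, 241 higher and 337 lower. Csf1r had a value of -0.28 ± 0.16 (adjusted p = 0.496), Adgre1 one of -0.31, Cd68 one of -0.31 and C1qa one of -0.19. The resident macrophage list had a median of -0.17, with 0 members called by edgeR over all genes (adjusted p = 0.146). Pde2a was at 0.06 ± 0.13 (adjusted p = 0.897), Nppa at -1.58 ± 0.75 (adjusted p = 0.439), Nppb at -0.42, Myh7 at -0.06, Col1a1 at -0.09 and Postn at -0.23.

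Gene lists moved by small amounts in the hearts labelled PLX3397. Nuclear oxidative phosphorylation genes were lower as a list (median -0.19, adjusted p = 5.69e-12, and adjusted p = 0.488 with an estimated correlation). Their median was -0.12 without control replicate 3. Their score was -0.20, 0.08 and 0.12 in the controls and -0.09, -0.17 and -0.30 in the PLX3397 libraries. Control replicate 1 thus lay below PLX3397 replicates 1 and 2. The list of 21 integrated stress response genes was lower (median -0.35, adjusted p = 5.47e-05, and adjusted p = 0.268 with an estimated correlation). Of its members, 4 fell when adjusted over the list alone. The list of 22 NRF2 and antioxidant genes was lower as well (median -0.19, adjusted p = 0.00282, and adjusted p = 0.376 with an estimated correlation). The 10 genes of kinases that sorafenib targets were higher as a list (median 0.23, adjusted p = 0.00442; adjusted p = 0.376 with an estimated correlation). Their score was 0.27, -0.03 and -0.24 in the controls and 0.24, 0.25 and 0.21 in the PLX3397 libraries, so control replicate 1 lay above all 3 of these. The median was 0.15 without control replicate 3 and 0.11 without PLX3397 replicate 3. Kdr, Flt1 and Flt4 of this list are also among the 18 endothelial markers, which were higher as well, 13 of them above 0 (median 0.16, adjusted p = 0.0354; adjusted p = 0.394 with an estimated correlation). Endothelial markers did not pass without control replicates 1 (0.17) and 2 (0.13) or PLX3397 replicate 3 (0.08), each left out alone, with the stricter filter (0.16) or with limma on FPKM (0.12). The 33 interferon-stimulated genes were higher as a list too (median 0.19, adjusted p = 0.0175, and adjusted p = 0.626 with an estimated correlation). The interferon median was 0.31 without PLX3397 replicate 3. The interferon list did not pass without control replicate 1 (0.24), control replicate 2 (0.14), PLX3397 replicate 1 (0.07) or PLX3397 replicate 2 (0.17).

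The comparison of both agents with sorafenib asks what PLX3397 changed in hearts that also received sorafenib. Single genes did not pass. As lists, macrophage markers were lower and clock genes were shifted with the preset correlation only, with adjusted p = 0.268 and 0.246 with an estimated correlation. edgeR called 0 genes with 1216 at an unadjusted p under 0.05 and a smallest adjusted p of 0.160. DESeq2's Wald test called 65, 28 higher and 37 lower, and limma on FPKM called 0. The count was 2 without sorafenib replicate 2, 1 without sorafenib replicate 3, 2 without replicate 1 of both agents and 1 without replicate 3 of both agents. Csf1r had a value of -0.73 ± 0.17 (adjusted p = 0.435) and C1qa one of -0.80 ± 0.22 (adjusted p = 0.573), and of the alternatives only DESeq2's Wald test called both. Adgre1 was at -0.51, Cd68 at -0.32 and Pde2a at -0.34 ± 0.13 (adjusted p = 0.715), with 57.6 ± 1.89 CPM (SD, n = 3) under both agents. Myh7 (0.36), Nppb (0.34), Col1a1 (-0.32) and Postn (-0.58) did not pass. Nppa was at -1.10 ± 0.74 and at 0.41 without sorafenib replicate 1.

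Resident macrophage markers had a median of -0.55 in hearts with both agents against sorafenib (adjusted p = 2.11e-18; adjusted p = 0.268 with an estimated correlation). It was -0.27 without sorafenib replicate 3, the sorafenib library with the highest marker level. Of the 30 markers, 10 fell when adjusted over the list alone and 0 were called by edgeR over all genes. Matrix and fibrosis genes were lower (median -0.36, adjusted p = 4.35e-11; adjusted p = 0.268 with an estimated correlation), 3 of 28 adjusted over the list alone. Their score was 0.12, -0.53 and -0.09 with sorafenib and -0.50, -0.89 and -0.40 with both agents, so the groups overlapped. Adipocyte markers varied between the same libraries. Their score was 0.762, -1.032 and 0.205 with sorafenib and -1.423, -1.405 and 0.574 with both agents. Whether differences in the tissue sampled gave these values was not tested. The 12 fibroblast markers moved with the matrix genes, 11 of them below 0 and 0 called by edgeR over all genes or adjusted over the list alone (median -0.22, adjusted p = 0.00364; adjusted p = 0.577 with an estimated correlation). That list did not pass without sorafenib replicate 1 (-0.03) or replicate 2 of both agents (-0.14), and was at -0.40 without sorafenib replicate 2. Clock genes were shifted (median 0.47, adjusted p = 3.08e-06; adjusted p = 0.246 with an estimated correlation), with 10 higher and 3 lower of 16 adjusted over the list alone. Interferon-stimulated genes were lower (median -0.28, adjusted p = 4.82e-05; adjusted p = 0.462 with an estimated correlation), at -0.12 without sorafenib replicate 2. B cell markers (median 0.80, adjusted p = 5.37e-07) and neutrophil markers (median 0.96, adjusted p = 1.36e-06) were higher, with adjusted p = 0.346 and 0.246 with an estimated correlation. The neutrophil median was 1.54 without replicate 1 of both agents. Atrial and conduction genes had a median of -1.43 (adjusted p = 0.000344; adjusted p = 0.443 with an estimated correlation). That list did not pass without sorafenib replicate 1, at -0.31, and its score was 1.17 in that library against -1.71 and -1.36 in the other sorafenib libraries. Its median was -2.26 without replicate 3 of both agents.

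The comparison of both agents with PLX3397 asks what sorafenib changed in hearts that also received PLX3397. Macrophage, antigen-presentation and cell cycle genes were lower, clock genes changed in both directions, and Cyp1a1 rose, as without PLX3397. Lists of interferon-stimulated and of matrix genes were lower in this pair of groups, and 3 of 18 cardiomyocyte markers rose. No list passed with an estimated correlation. The test called 611 genes, 190 higher and 421 lower, of which 232 changed at least 2-fold. With limma on the deposited FPKM, which moved the median of all genes by -0.10, the split was 78 higher and 543 lower of 621 called.

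Csf1r fell by 1.62 on the log2 scale (SE 0.17, adjusted p = 0.000383), C1qa by 1.88 (SE 0.23, adjusted p = 0.00171) and Adgre1 by 1.18 (SE 0.27, adjusted p = 0.0356). Cd68 was at -0.59 ± 0.22 (adjusted p = 0.211). Folr2 (-3.76), Timd4 (-3.75), Cx3cr1 (-2.59), Slamf9 (-2.36), Fcrls (-2.02), Cd163 (-1.96), Ltc4s (-1.96) and Cybb (-1.85) fell. Of 30 resident macrophage markers, 21 fell and 0 rose over all genes, and 27 fell when adjusted over the list alone (median -1.29, adjusted p = 1.59e-59; adjusted p = 0.0849 with an estimated correlation). Cd74 (-1.39), H2-Aa (-1.39), H2-Eb1 (-1.34) and H2-Ab1 (-1.24) fell, 4 of 16 dendritic cell and MHC class II genes, of which 8 fell when adjusted over the list alone (median -1.0, adjusted p = 5.37e-07; adjusted p = 0.374 with an estimated correlation). The chemokine gene Ccl9 fell (-1.51), as did the mast cell protease gene Cpa3 (-2.43). Among 33 interferon-stimulated genes 5 fell, Rtp4 (-0.99), Bst2 (-0.86), Oas1a (-1.40) and Cxcl9 (-1.15) among them, and 14 fell when adjusted over the list alone (median -0.43, adjusted p = 7.32e-12; adjusted p = 0.297 with an estimated correlation).

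Ccna2 (-1.93), Top2a (-1.81), Mki67 (-1.63) and Tpx2 (-1.61) fell. Of 29 cell cycle genes, 14 fell and 1 rose over all genes, and 25 fell and 1 rose when adjusted over the list alone (median -1.35, adjusted p = 2.08e-27; adjusted p = 0.173 with an estimated correlation). Clock genes that rose were Ciart (3.25 ± 0.29, adjusted p = 0.000119), Per2 (2.31), Dbp (2.10), Per3 (1.75), Tef (1.33), Hlf (1.29) and Nr1d2 (0.77), while Arntl fell (-2.41). Of 16 clock genes, 9 rose and 3 fell over all genes, and 10 rose and 4 fell when adjusted over the list alone (median 0.87, adjusted p = 2.72e-17; adjusted p = 0.0849 with an estimated correlation). Cyp1a1 rose by 2.50 ± 0.31 (adjusted p = 0.00354), Inmt by 1.48 and the glucocorticoid-responsive gene Klf9 by 0.43. The chaperone genes Sdf2l1 (-1.42) and Hyou1 (-0.85) fell, 2 of 19 unfolded protein response genes, of which 13 fell and 1 rose when adjusted over the list alone (median -0.41, adjusted p = 5.93e-08; adjusted p = 0.376 with an estimated correlation). Erythroid genes had a median of 0.88, with 0 called by edgeR over all genes and 6 of 8 risen when adjusted over the list alone (adjusted p = 1.26e-07; adjusted p = 0.268 with an estimated correlation).

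Among matrix genes, Sparc (-0.67), Col4a1 (-0.84), Loxl1 (-0.55) and Tgfb1 (-0.56) fell. They were 4 of the 6 called of 28 matrix and fibrosis genes, of which 11 fell when adjusted over the list alone (median -0.42, adjusted p = 7.29e-10; adjusted p = 0.268 with an estimated correlation), with a median of -0.27 without replicate 2 of both agents. Col1a1 (-0.30) and Postn (-0.49) did not pass. Atrial and conduction markers had a median of -0.86, with 10 of 10 below 0 and 0 called by edgeR over all genes or adjusted over the list alone (adjusted p = 0.00364; adjusted p = 0.513 with an estimated correlation), and were at -1.64 without replicate 3 of both agents. Endothelial genes Kdr (-0.78), Emcn (-0.38) and Egfl7 (-0.43) fell and Sox17 rose (0.62). Of 18 endothelial markers, 5 fell and 1 rose over all genes and adjusted over the list alone (median -0.12, adjusted p = 0.0233; adjusted p = 0.376 with an estimated correlation). That list did not pass without replicate 3 of PLX3397 or of both agents, at -0.06 each. Kdr and the pericyte gene Pdgfrb (-0.57), which fell, encode kinases that sorafenib targets. They were the 2 called of 10 such genes, of which 4 fell when adjusted over the list alone (median -0.17, adjusted p = 0.0164; adjusted p = 0.394 with an estimated correlation). This list did not pass without PLX3397 replicate 3 (-0.15) or with limma on FPKM (-0.13), and was at -0.33 without replicate 2 of both agents. The cardiomyocyte genes Tcap (1.02), Tnnt2 (0.42) and Actn2 (0.36) rose, 3 of 18 markers, of which 6 rose when adjusted over the list alone (median 0.21, adjusted p = 9.20e-07; adjusted p = 0.246 with an estimated correlation). Myh7 rose (0.66 ± 0.15, adjusted p = 0.0341), and so did Aldoa (0.33), of glycolysis. Pde2a was at -0.03 ± 0.13 (adjusted p = 0.939), Nppa at 0.56 ± 0.74 and Nppb at -0.11 ± 0.46.

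The count of 611 fell when any of the libraries compared was left out. It was 204 without PLX3397 replicate 1, 314 without replicate 2 and 358 without replicate 3 of that group. It was 177 without replicate 1, 391 without replicate 2 and 313 without replicate 3 of the group with both agents. Of 52 called genes named here by rule, 27 were called in every alternative other than that limit, among them Csf1r, C1qa, Folr2, Timd4, Top2a, Mki67, Arntl, Ciart, Cyp1a1, Sparc and Tcap.

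The effect of sorafenib without PLX3397 and that with it came from separate libraries and could be set side by side. Of the 500 genes called without PLX3397, 486 (97.2%) had the same sign with it, and of the 611 called with PLX3397, 593 (97.0%) had the same sign without it. Both comparisons called 59 genes higher, against 2.85 for independent lists, and 133 lower, against 4.81. Both came from 1 fit with a shared spread, so genes of low spread are more easily called in both. The overlap by chance may thus be larger than for independent lists. Across all 18897 genes the correlation of both effects was 0.272 (Spearman's rho 0.400), where genes are not independent replicates. It was 0.0924 without a filter on low counts, 0.564 with a stricter filter, 0.513 with limma on FPKM and 0.530 with counts divided by 4. Leaving out 1 library gave 0.0331 to 0.218, with the filter on low counts run again, so the set of genes changed as well. The part of the filter and that of the library cannot be told apart. The correlation was 0.0331 without PLX3397 replicate 1, 0.148 without control replicate 1 and 0.160 without replicate 1 of both agents. It was 0.181, 0.180 and 0.163 without sorafenib replicates 1, 2 and 3. The effect of PLX3397 without and with sorafenib had a correlation across genes of 0.117 (Spearman's rho 0.157). The filters gave 0.0262 and 0.290, limma on FPKM 0.187 and counts divided by 4 0.233. It was 0.0386 and 0.0730 without control replicates 1 and 2, and 0.0520, 0.0321 and 0.0735 without PLX3397 replicates 1, 2 and 3. Without sorafenib replicates 2 and 3 it was 0.0488 and 0.0584, and without replicates 1 and 3 of both agents 0.0641 and 0.0470. Each library was left out alone, with the filter run again.

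**Figure D3:**
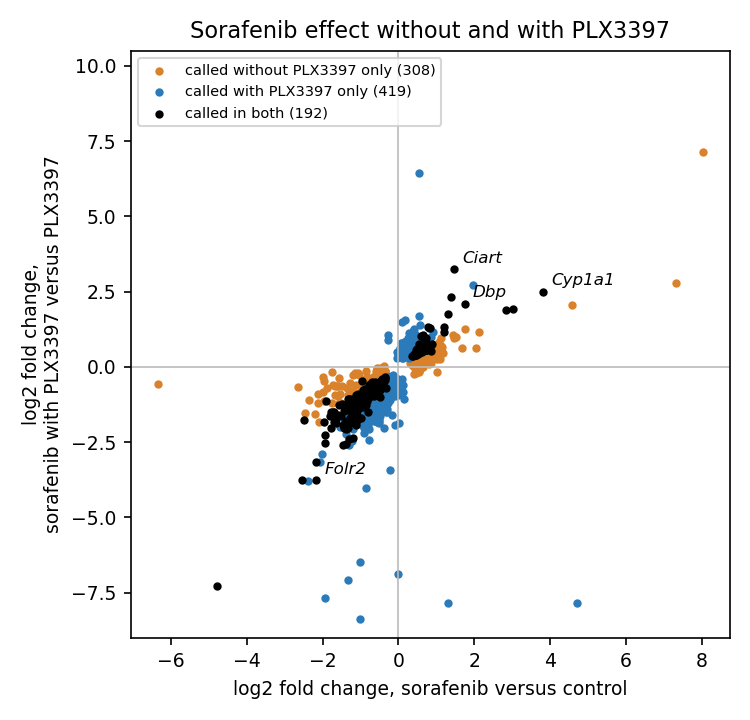
Log2 fold change of sorafenib with PLX3397 versus PLX3397 (vertical axis) against that of sorafenib versus control (horizontal axis) for genes called in either. Of the plotted genes, 192 were called in both comparisons and lay in the same direction.

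The interaction asks whether the sorafenib effect differed with PLX3397. edgeR called 0 genes with 1099 at an unadjusted p under 0.05 and a smallest adjusted p of 0.530, and DESeq2's Wald test called 5. The count was 1 without PLX3397 replicate 1, 2 without sorafenib replicate 2 and 2 without replicate 1 of both agents. Pde2a had an interaction of -0.40 (adjusted p = 0.822), from 0.37 ± 0.13 without PLX3397 to -0.03 ± 0.13 with it. The macrophage list had a median of -0.43 (adjusted p = 1.91e-06; adjusted p = 0.488 with an estimated correlation), which did not pass without sorafenib replicate 3, at -0.16. The matrix list had a median of -0.33 (adjusted p = 1.36e-06; adjusted p = 0.376 with an estimated correlation), at -0.10 without sorafenib replicate 1. Nuclear oxidative phosphorylation genes had one of 0.20 (adjusted p = 1.06e-10; adjusted p = 0.532 with an estimated correlation), at 0.13 without control replicate 3. In all, 15 lists passed with the preset correlation.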

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

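The tests of macrophage markers, of clock genes and of other splits of the libraries were chosen after the results were seen. The positions of control and PLX3397 replicate 1 were predicted before they were computed, but the requirement that the median over genes point the same way was added after they were seen.

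The sorafenib effect with PLX3397 differed from that without it in 15 gene lists, by a test of the interaction with camera's preset correlation. None of the 15 passed with an estimated correlation (adjusted p = 0.346 to 0.671) or with fry. Median interactions were negative for resident macrophage markers (-0.43), interferon-stimulated genes (-0.41), matrix and fibrosis genes (-0.33), kinases that sorafenib targets (-0.27), cyclic nucleotide phosphodiesterases (-0.18), cell cycle genes (-0.14) and cyclic nucleotide signalling genes (-0.12). They were positive for neutrophil markers (0.69), B cell markers (0.69), erythroid genes (0.48), clock genes (0.37), integrated stress response genes (0.37), nuclear oxidative phosphorylation genes (0.20), NRF2 and antioxidant genes (0.18) and glycolysis genes (0.14). Without sorafenib replicate 3 the macrophage list did not pass, at -0.16. Matrix genes were at -0.10 without sorafenib replicate 1 and oxidative phosphorylation genes at 0.13 without control replicate 3. B cell markers were at 0.35 without control replicate 3 and at 0.40 without PLX3397 replicate 3. Phosphodiesterase genes were at -0.09 without control replicate 3, -0.11 without sorafenib replicate 2 and -0.30 without replicate 2 of both agents. Integrated stress response genes were at 0.24 without sorafenib replicate 2 and 0.21 without replicate 3 of both agents. Without replicate 3 of both agents the NRF2 list did not pass, at 0.14. Clock genes did not pass without control replicate 1 (0.33), control replicate 2 (0.32), PLX3397 replicate 1 (0.30), sorafenib replicate 3 (0.32) or replicate 1 of both agents (0.25). Cell cycle genes did not pass without control replicate 2 (-0.17), PLX3397 replicate 1 (-0.04), sorafenib replicate 3 (-0.24) or replicates 1 (-0.11) and 2 (-0.16) of both agents. They passed at larger values without control replicates 1 (-0.27) and 3 (-0.32), PLX3397 replicates 2 (-0.29) and 3 (-0.24), sorafenib replicate 2 (-0.24) or replicate 3 of both agents (-0.31). Erythroid genes did not pass without replicate 1 of control (0.51), PLX3397 (0.42), sorafenib (0.39) or both agents (0.19). Neutrophil markers did not pass without control replicate 1 (0.66), PLX3397 replicate 3 (0.51), sorafenib replicates 1 (0.42) and 2 (0.59), or replicates 2 (0.77) and 3 (0.60) of both agents. Cyclic nucleotide signalling genes did not pass without control replicates 2 (-0.08) and 3 (-0.09), PLX3397 replicates 2 (-0.11) and 3 (-0.05), sorafenib replicate 1 (-0.07), or replicates 1 (-0.13) and 3 (-0.09) of both agents. Glycolysis genes did not pass without control replicates 2 (0.15) and 3 (0.11), PLX3397 replicates 1 (0.16) and 2 (0.08), sorafenib replicates 1 (0.10) and 3 (0.14), or replicate 1 of both agents (0.07). In each case 1 library was left out at a time. For single genes edgeR called 0 in the interaction with 1099 at an unadjusted p under 0.05, and DESeq2 called 5. Because the real split called 0, all 20 splits of the libraries tried were as large by construction, which decides nothing; the highest called 4.

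Macrophage markers were lower in the hearts labelled sorafenib than in those labelled PLX3397, the agent meant to clear these cells. The fall did not hang on the choice among the scalings tried. The median of the 30 markers was -0.88 or lower under the FPKM, DESeq2 and mitochondria-free scalings. These moved the median of all genes by -0.11, 0.009 and 0.001, too little to remove such a fall, so the test could not decide on scaling. Endothelial and fibroblast markers argued against a lower share of all cells other than cardiomyocytes. The lower of their medians was -0.0541, above the upper quartile of the macrophage markers at -0.60. The other leukocyte lists also had medians below 0, from -0.41 for monocyte markers to -1.08 for dendritic cell and MHC class II genes. Of these, B cell markers and the dendritic cell and MHC class II genes passed with the preset correlation. A lower share of leukocytes in general was not tested. An exchange of the sorafenib and PLX3397 labels cannot be told apart from an effect of sorafenib on macrophages, since the libraries labelled PLX3397 had a median of -0.17 and an exchange would rename the sorafenib comparisons without changing their values. A loss of cardiac macrophages under sorafenib, or a lower expression of these genes in them, may also explain the pattern and was not tested.

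Leaving out PLX3397 replicate 1 raised the count between PLX3397 and control from 0 to 578. Of the 10 splits of these 6 libraries, the one that set control replicate 1 with PLX3397 replicates 2 and 3 called 448 genes. The real one called 0. That split was the highest of the 10 and was picked after the counts were seen. By itself it does not show a structure of the samples beyond the labels. On 1903 genes called between the remaining libraries, control replicate 1 lay at 0.295 and PLX3397 replicate 1 at 0.219 on a scale from 0 (controls) to 1 (PLX3397), but at 0.611 and 0.410 by the median over genes. The weighted position met the prediction for a PLX3397 library without the effect, and the median did not. An exchange of both libraries would put control replicate 1 nearer to the PLX3397 end. Its median of 0.611 lay there, and its weighted position of 0.295 did not. On the first principal component control replicate 1 lay at -41.8. The other controls lay at -41.0 and -55.7 there, and PLX3397 replicates 2 and 3 at 6.66 and 6.07. The 1903 genes were picked on the remaining libraries, so a library left out may fall towards the middle of the scale. Because the measures place control replicate 1 differently, neither explanation was settled. No biological explanation was tested.

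Clock genes changed in both comparisons of sorafenib. A scaling difference that moves all genes one way cannot by itself give changes in both directions. At least 2 called members went in the rarer direction under each scaling and in both comparisons. Both directions were known when this test was chosen, and the scalings moved all genes too little to change them. Biases that differ between genes were not tested. Arntl fell by 1.31 on the log2 scale, against the rise of Dbp, as a shift of the clock's phase would give. A different time of day of sampling may give the same values as an effect of sorafenib on the clock, and they cannot be told apart because the labels give no time.

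With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 500 genes for sorafenib versus control against at most 1 in the others (1 of the 10 as large). It called 611 against at most 2 for both agents versus PLX3397, and 3046 against 0 for both agents versus control. For both agents versus sorafenib and for PLX3397 versus control the real split called 0, so all 10 were as large by construction, which decides nothing. The highest for both agents versus sorafenib, which set sorafenib replicates 1 and 3 with replicate 3 of both agents, called 67.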

How the results depend on the processing

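Counts divided by 4, the removal of mitochondrial genes and the comparison of both agents with control were chosen after the data were seen. The cause of a change was not tested unless stated.

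For sorafenib versus control, 500 genes became 772 with a stricter filter, 1739 with DESeq2's Wald test, 971 with limma on FPKM, 912 with counts divided by 4, 221 with the replicate block and 136 with a limit of 2-fold, which by construction removes calls. For both agents versus PLX3397, 611 became 1207 with DESeq2 and 232 with the 2-fold limit, and 3046 for both agents versus control became 890 with that limit. DESeq2 called 100 genes for PLX3397 versus control, 65 for both agents versus sorafenib and 5 for the interaction, where edgeR called 0, and edgeR on only the groups compared called 1 for PLX3397 versus control. Of the gene list tests, 69 passed with the preset correlation, 0 with an estimated one and 9 with fry.

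The correlation across genes of the sorafenib effect, 0.272, became 0.0924 without a filter, 0.564 with the stricter filter, 0.513 with limma on FPKM and 0.530 with counts divided by 4. That of the PLX3397 effect, 0.117, became 0.0262, 0.290, 0.187 and 0.233 under the same settings and 0.165 with DESeq2.

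Leaving out 1 library gave 27 to 1422 genes for sorafenib versus control, 0 to 578 for PLX3397 versus control, 0 to 2 for both agents versus sorafenib, 177 to 391 for both agents versus PLX3397, 1261 to 3274 for both agents versus control and 0 to 2 for the interaction. The correlation of the sorafenib effect ranged from 0.0331 to 0.218 and that of the PLX3397 effect from 0.0321 to 0.149. In these fits the filter on low counts was run again, so the set of genes changed as well. Nppa in both agents versus sorafenib, at -1.10, reversed to 0.41 without sorafenib replicate 1 and was at -1.55 without sorafenib replicate 3, and Nppb in both agents versus control ranged from -0.83 to 0.36. With limma on FPKM the median of fatty acid genes reversed for sorafenib versus control (-0.0496), as did that of oxidative phosphorylation genes for both agents versus PLX3397 (-0.0195). That scaling moved the median of all genes by -0.11 and -0.10 in these comparisons.

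For named genes, 2962 values under alternatives stayed on their side of the threshold without a reversal. Another 322 lost a call, 8 gained one and 2 reversed. A change of sign counted as a reversal only if either value was called or both lay more than their SE from 0. Other changes of sign are thus among the 2962, as for Nppa in sorafenib versus control. For the list tests that passed, 879 values stayed, 236 lost a call and 2 reversed; gains by other lists are not in this tally, and 63 to 73 list tests passed when 1 library was left out. The replicate numbers did not pair the libraries: same-numbered libraries had a mean correlation of -0.01 in their deviations from group means, and 0 of 12 correlated best with their own number. Other pseudocounts and scalings planned for FPKM as the main unit were not run, because counts were the main unit. Whether the deposited counts are of single fragments is not known, so the depth in fragments is not known either.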

Other observations

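The comparison of both agents with control was added after the other results had been seen, and so were its tests.

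Hearts with both agents differed from controls in 3046 genes by edgeR, 1507 higher and 1539 lower, and 890 of them changed at least 2-fold. With limma on FPKM, which moved the median of all genes by -0.13, the split was 520 higher and 2542 lower. The count was 1681 without control replicate 2, 1261 without control replicate 3, 1289 without replicate 1 of both agents and 1781 without replicate 2 of both agents. Csf1r (-1.90), Adgre1 (-1.49), Cd68 (-0.89) and C1qa (-2.07) fell, and 25 of 30 resident macrophage markers fell. Timd4 (-3.88), Cx3cr1 (-2.39), Slamf9 (-2.44) and Atf3 (-2.26) fell as well. Cyp1a1 (4.01), Ciart (2.70), Dbp (2.37), Zbtb16 (2.27) and Bmp4 (1.61) rose. Of 18 cardiomyocyte markers 10 rose, and Myh7 rose by 0.60. Of 29 cell cycle genes 24 fell and 1 rose, and of 28 matrix genes 10 fell and 1 rose. Of 12 fibroblast markers 3 fell, and 5 fell and 1 rose when adjusted over the list alone (median -0.31, adjusted p = 0.0381; adjusted p = 0.680 with an estimated correlation). Pde2a was at 0.02 (adjusted p = 0.935).

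Several lists passed with the preset correlation but lost the call when 1 library was left out. In sorafenib versus control, B cell markers had a median of -0.98 and did not pass without control replicate 3 (-0.38) or sorafenib replicate 1 (-0.76). Erythroid genes had one of 0.42 and did not pass without control replicate 2 (0.31) or sorafenib replicate 3 (0.18). Cyclic nucleotide signalling genes had one of 0.13 and did not pass without control replicate 2 (0.14), control replicate 3 (0.13) or sorafenib replicate 1 (0.10).

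In both agents versus sorafenib, cell cycle genes had a median of -0.22 and did not pass without sorafenib replicate 3 (-0.17) or replicate 2 of both agents (-0.17), and had one of -0.36 without sorafenib replicate 2 and of -0.44 without replicate 3 of both agents. Dendritic cell and MHC class II genes had one of -0.31 and did not pass without sorafenib replicate 3 (-0.15) or replicates 1 (-0.22) and 3 (-0.13) of both agents, and had one of -0.58 without replicate 2 of both agents. Mast cell markers had one of -0.97 and did not pass without sorafenib replicate 3 (-0.25) or replicates 1 (-0.58) and 3 (-0.59) of both agents. Cardiomyocyte markers had one of 0.13 and did not pass without replicate 1 of sorafenib (0.08) or of both agents (0.07). Glycolysis genes had one of 0.10 and did not pass without replicate 1 of both agents (0.04).

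In PLX3397 versus control, dendritic cell and MHC class II genes had a median of -0.44 and did not pass without control replicates 2 (-0.45) and 3 (-0.34) or PLX3397 replicate 3 (-0.17). Erythroid genes had one of -0.35 and did not pass without control replicates 1 (-0.24) and 3 (-0.24) or PLX3397 replicate 1 (-0.20). None of the lists in these paragraphs passed with an estimated correlation.

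Cyp1a1, named here after its values were seen, had 9.85, 12.1 and 12.3 CPM in PLX3397 replicates 1 to 3, against 3.21, 5.62 and 3.16 CPM in the controls (log2 fold change 1.51, adjusted p = 0.361).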
